A study of Aspergillus luchuensis with 6 samples.

How the data were processed

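RNA from rice koji of wild-type *Aspergillus luchuensis* RIB2601 and of its mutant U1 was sequenced in 3 libraries per strain, per the labels. The labels do not say whether the libraries of a strain came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The submitters' processing notes name Trimmomatic 0.32, a read trimmer, and BWA 0.7.12, a read aligner. The counting program, the genome build, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The aligner named does not split reads across introns, so reads over exon junctions may be under-represented in the counts. Reads shared by similar or overlapping genes cannot be told apart in these values.

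The authors deposited 1 table per library with raw counts per locus tag, without normalization: whole numbers with a different total in each library. All 6 tables held the same 11488 tags. No gene names accompany the tags. A reference table of 12941 genes from another annotation of the species was searched in its identifier columns, and 0 of the tags matched. The 21 gene lists fixed before the data were examined (amylolytic enzymes, other hydrolases, transport, central metabolism, secretion, stress, conidiation as a marker of spore-forming cells, and others) therefore had no members, and the planned tests of those lists (camera and fry) were not run. No positions, gene lengths or GC content are given for the tags.

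Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 being loaded with it. Tags were kept by edgeR's filterByExpr on the 2 strains, which left 8790 tags holding 99.86% to 99.88% of the counts of each library. Libraries were scaled with trimmed-mean (TMM) factors, which ran from 0.970 to 1.043. Strains were compared with a robust quasi-likelihood fit on strain alone and a two-sided test, Benjamini-Hochberg adjusted over all tested tags, and called at an adjusted p under 0.05. Levels are CPM, counts divided by library size in units of 1000000, on TMM-scaled library sizes, as mean ± SD over 3 libraries. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of the F statistic. For tags unread in wild type, fitted fold changes depend on the prior count, and a lower bound was computed instead against 3 counts over the summed wild-type libraries. The floor of 3 counts corresponds to 0.356 to 0.759 CPM in a single library. These floors cover counting error only, while the standard errors also take in the spread between libraries.

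The tags to be named were set before the data were examined. Without gene names the rule gave the 2 rising and 2 falling tags with the largest absolute log2 fold change among called tags with separated libraries and a mean of at least 10 CPM. The grouping along tag numbers and the set of 100 most abundant tags were added after the values had been seen. Runs were tested with 10000 shuffles of the tag order.

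Libraries of a strain were checked for having been deposited more than once. The chi-square statistic over its degrees of freedom, for tags with at least 10 summed reads, was 2.15 to 3.25 between wild-type and 3.76 to 7.46 between U1 libraries, so each pair differed by more than sampling noise and all 6 libraries were counted. The code was tested on simulated data: 8790 tags were drawn at the real means and library sizes with a seeded set of 200 changed. For the comparison of U1 with wild type, 70.1% of the simulated changes of 1.5-fold, 95.5% of those of 2-fold and 98.5% of those of 4-fold were recovered, and 2.2% of the calls were false. The spread of each simulated tag followed the trend with level, without tags of unusual spread. Far fewer tags were changed than the 2153 called in the data. These rates may therefore be optimistic.

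The alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, upper-quartile scaling, DESeq2's Wald test, no filter on low counts, a filter of 10 CPM in 3 libraries, the replicate number as a block, library sizes without the 10 most abundant tags, an adjusted p under 0.01, and leaving out each library. Thinning to the smallest library, library totals alone, and library sizes without the tags of the longest rising and falling run were added later.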

Results

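Transcript levels were measured by RNA sequencing in *Aspergillus luchuensis*, a filamentous fungus grown on steamed rice to make koji, the starter of Japanese distilled spirits, in which its secreted amylases break rice starch down to sugars. The libraries came from rice koji of the strain RIB2601 and of U1, a mutant that the labels describe as degrading starch strongly and that the series title traces to ion beam mutagenesis. There were 3 wild-type and 3 U1 libraries. The gene counts summed to 5064126, 4324302 and 4025119 in the wild-type replicates 1 to 3 and to 8420828, 5482341 and 4427719 in the U1 replicates 1 to 3. Between 10184 and 10363 of the 11488 locus tags had at least 1 read in a library. The deposited counts carry locus tags without gene names, and 0 of these tags occur in the reference table used here, so genes are described by tag, level and place in the numbering. For the same reason the amylase, protease, sugar transport and other gene lists fixed in advance could not be filled, and no value for a named amylase is given.

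The comparison of U1 with wild type asked which transcripts differ between the mutant and its background strain. Of 8790 tags tested, 2153 (24.5%) changed at an adjusted p under 0.05, with 1002 higher and 1151 lower in U1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Most of these changes were small. The median absolute log2 fold change of the called tags was 0.59, and 493 tags changed by at least 2-fold, 236 upward and 257 downward. A change of at least 4-fold was found for 59 rising and 49 falling tags. In 2109 of the 2153 called tags, all 3 U1 libraries lay on one side of all 3 wild-type libraries. Such a separation was seen in 37.7% of the tested tags, against 10% by chance. Replicates lay close together, with a biological coefficient of variation (edgeR's name for the spread between libraries) of 7.3%. Pearson correlations across tags (log2 scale) between libraries of a group were 0.991 to 0.9926, where tags are not independent replicates. The labels do not say whether the libraries of a strain came from separate cultures, so this spread may be technical. The first principal component held 74.2% of the variance and separated the strains. The balance of directions changed with library totals alone, in place of trimmed-mean factors: 1385 tags were higher and 899 lower in U1. The median log2 fold change of all tested tags then moved only from 0.005 to 0.077. With DESeq2 size factors 1007 tags were higher and 1144 lower, and with upper-quartile scaling 1019 were higher and 1115 lower.

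**Figure D1:**
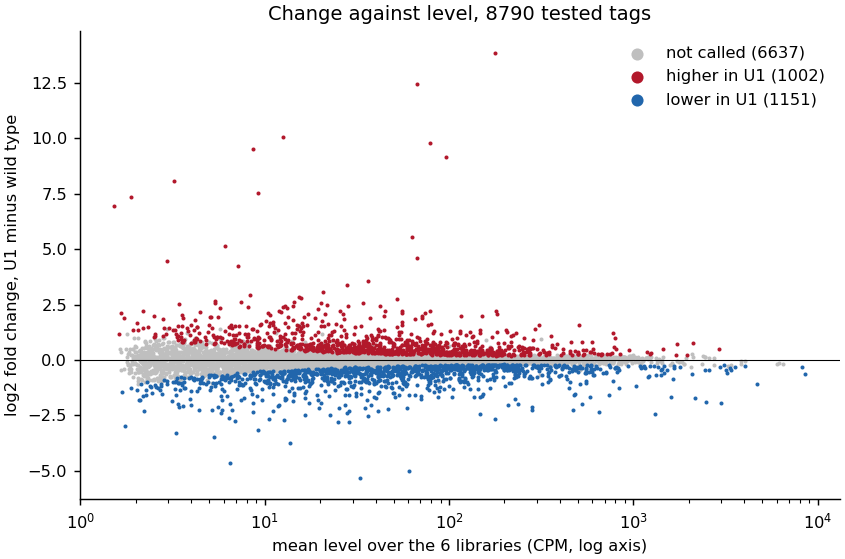
Log2 fold change (U1 minus wild type) of each of the 8790 tested tags against its mean level in normalised counts (CPM) over the 6 libraries, on a log axis; colours mark the 1002 tags called higher, the 1151 called lower and the 6637 not called. The tags above a log2 fold change of 4 stand apart from the rest, and most called tags lie near 0; fitted values of tags without wild-type reads depend on the prior count.

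Highly expressed transcripts fell more often than they rose. Among the 100 tags with the highest mean level, all at 1070 CPM or more, 40 fell, 9 rose and 51 did not pass the test. Of those that changed by at least 2-fold, 6 fell and 0 rose. The remaining called tags were more evenly divided, with 993 rising and 1111 falling, and the direction of the called tags differed between these sets (two-sided Fisher's exact test across tags, p = 5.97e-05, tags not being independent). With library totals alone, 34 of the 100 fell and 11 rose. The remaining called tags then rose more often, with 1374 rising and 865 falling (two-sided Fisher's exact test between the sets, p = 1.29e-06). Their near-even split in the main fit thus rests on scaling beyond library totals. When 1 library was left out, from 29 (without wild-type replicate 1 or 2) to 53 (without U1 replicate 1) of the 100 fell. The number that rose then ran from 5 (without wild-type replicate 3) to 9 (without U1 replicate 1 or 2). For shares of the counts, tags were ranked by raw counts summed over the 6 libraries, so these 100 need not be the same tags. The top 10 by that ranking took 6.0% to 6.1% of the counts in the wild-type libraries and 5.1% in each U1 library. The top 100 took 22.6% to 23.2% and 19.7% to 20.8%. In the fifth of the tags with the highest level, 131 CPM and above, 184 rose and 313 fell. In the fifth with the lowest level, from 1.53 to 11.4 CPM, 173 rose and 193 fell, and this group held 102 of the 236 tags that rose and 97 of the 257 tags that fell by at least 2-fold. Tags with few reads have larger standard errors, so small changes pass the test less often there.

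Among called tags with separated libraries and a mean of at least 10 CPM, the largest fitted rises were in transcripts without a wild-type read. AKAW_06019 had 0 reads in each wild-type library and 2797, 2085 and 1699 reads in the U1 libraries, a level of 356 ± 21.7 CPM (SD, n = 3). Against the level that 3 counts over the wild-type group would give (0.23 CPM), it was at least 1550-fold higher in U1 (edgeR adjusted p = 9.1e-15). AKAW_06020 also had 0 wild-type reads and reached 134.8 ± 7.2 CPM (SD, n = 3) in U1, at least 587-fold higher by the same floor (edgeR adjusted p = 2.53e-13). In U1 the first of these tags ranked 499th by level among all tags. Of all 11488 tags, 7 had no read in any wild-type library and a mean of at least 1 CPM in U1, and 1 tag showed the reverse. The floors cover counting error only.

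Among called tags under the same limits, the largest falls were in a pair of adjacent tags. AKAW_05447 went from 64.4 ± 11.6 CPM in wild type to 1.63 ± 0.264 CPM in U1 (SD, n = 3 each), with a log2 fold change of -5.31 ± 0.203 (SE; edgeR adjusted p = 7.08e-12). AKAW_05448 went from 118.5 ± 20 CPM to 3.51 ± 0.879 CPM (SD, n = 3 each), with a log2 fold change of -5.01 ± 0.172 (SE; edgeR adjusted p = 7.08e-12). The mean level was 39.5 times higher in wild type for the first and 33.8 times higher for the second. Both stood in a run of 4 neighbouring tested tags that all fell, by log2 fold changes of -2.24 to -5.31.

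Tags that changed were grouped along the tag numbers. This grouping was chosen after the values had been seen, and neighbouring numbers were taken as neighbours without a genome to place them on. A run was counted where 5 or more tested tags, next to each other in number once untested tags were passed over, were all called in one direction. There were 11 such runs, 2 rising and 9 falling, against a median of 0 and a maximum of 5 in 10000 shuffles of the tag order (permutation p = 0.0001, the smallest that these shuffles can give).

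The longest rising run held AKAW_06019 and AKAW_06020. It spanned 19 consecutive tags, of which 13 were tested and all 13 rose, as the definition of a run requires. The summed level of the 13 tags was 8.62 ± 1.68 CPM in wild type and 1180 ± 58.2 CPM in U1 (SD, n = 3 each), a 137-fold difference. The strains did not overlap (two-sided exact permutation tests of 3 against 3 libraries cannot go below p = 0.10). The run was chosen for tags called as rising, so this separation is favoured by the choice and is no separate support. Over the 3 wild-type libraries the run received 113 reads, of which 102 fell on 2 of its tags, and 7 of its tags received none. Those 7 were the same 7 tags that U1 alone expressed at 1 CPM or more. They passed the filter on their U1 reads alone, so they could only rise. With tags unread in wild type set to their lower bounds, which ran from 13.3-fold to 1550-fold, the median log2 fold change of the run was 6.23. The 6 untested tags inside the run had no wild-type reads and at most 11 reads summed over U1. The nearest tested tags outside did not pass the test, at log2 fold changes of 0.40 ± 0.207 before and -0.12 ± 0.118 after the run (SE; edgeR adjusted p = 0.186 and 0.543).

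The longest falling run also held 13 tags, consecutive in number and mostly abundant. The median level of its tags was 471.1 CPM in wild type and 103.9 CPM in U1. The log2 fold changes ran from -2.28 to -0.42 with a median of -1.95, and 10 of the 13 tags fell by at least 2-fold. The run took 1.52% ± 0.13 of all counts in wild type and 0.437% ± 0.0425 in U1 (SD, n = 3 each). Its summed level was 3.67 times higher in wild type, at 15700 ± 1430 against 4270 ± 488 CPM (SD, n = 3 each). The strains again did not overlap, which the choice of tags called as falling favours.

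**Figure D2:**
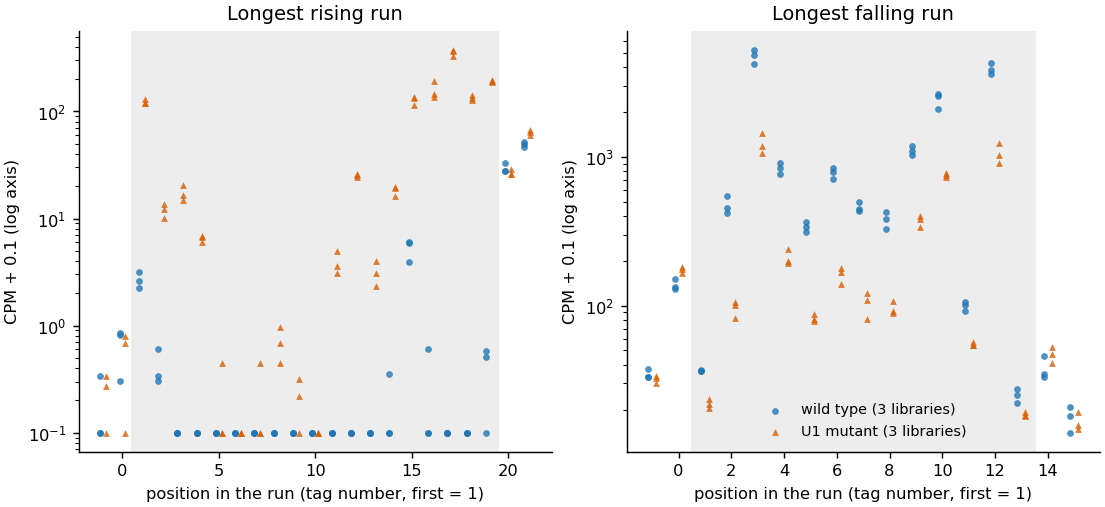
Level of each tag in the longest rising run (left) and the longest falling run (right), in CPM plus 0.1 on a log axis, against the tag's position in the run; circles are the 3 wild-type and triangles the 3 U1 libraries, grey marks the run, and 2 tags are shown on each side. Wild type sits at the lowest plotted value, which stands for 0 reads, in much of the left run, while in the right run the circles lie above the triangles.

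The other runs were smaller. The second rising run held 7 tested tags at a median log2 fold change of 1.44, from a median of 5.8 CPM in wild type to 14.9 CPM in U1. The other 8 falling runs held 5 to 8 tested tags each, with median log2 fold changes between -0.46 and -1.57. One of them was abundant, with a median level of 597.6 CPM in wild type and 408.3 CPM in U1, and its 5 tags fell by a median log2 fold change of -0.46.

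**Figure D3:**
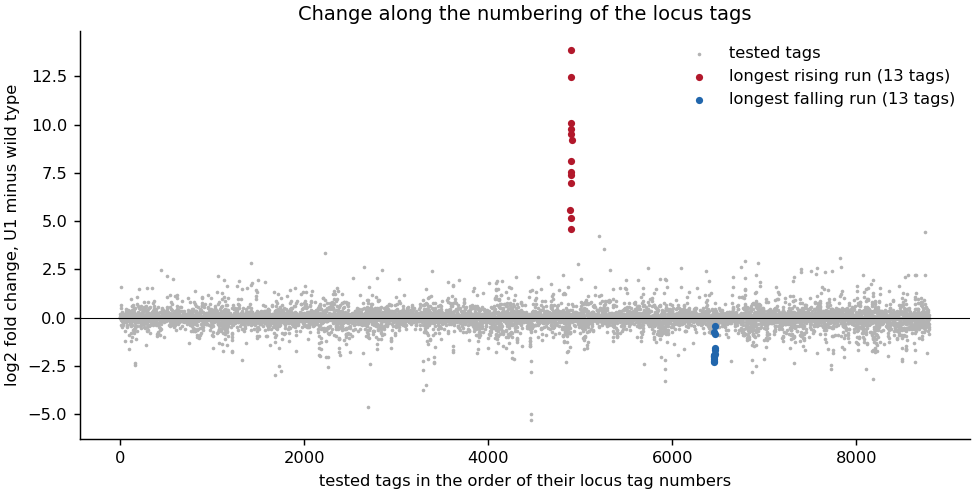
Log2 fold change (U1 minus wild type) of the 8790 tested tags, placed in the order of their locus tag numbers; grey points are single tags, red points the 13 tags of the longest rising run and blue points the 13 tags of the longest falling run. The red points, from 4.62 to 13.88 as fitted, share a single place in the order, and those without wild-type reads have fitted values that depend on the prior count.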

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

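Thinning to the smallest library, library totals alone, library sizes without the 2 longest runs, and every result on runs or on the 100 most abundant tags were chosen after the data had been seen. Over the 10 refits of all 6 libraries, between 1678 (DESeq2's Wald test) and 2284 (library totals alone) tags were called, against 2153. These refits kept from 75.8% of the original calls (1633 tags, Wald test) to 99.7% (2146 tags, DESeq2 size factors). Tags shared with the original calls kept their direction in every refit. At an adjusted p under 0.01 the count was 1416, as a stricter threshold gives. Leaving out 1 library called 1625 to 2069 tags and kept 73.2% to 84.9% of the original calls. The rising tags among the 100 most abundant then numbered from 5 (without wild-type replicate 3) to 9, and the cause was not tested. With library totals alone 60.6% of the calls were rises, against 46.5% in the main fit. The share was 46.8% with DESeq2 size factors and 47.8% with upper-quartile scaling. It was 48.2% without the 10 most abundant tags and 48.1% without the 2 longest runs in the library sizes. The balance between rises and falls thus moved mainly where library totals were used without a further factor. In all refits at an adjusted p under 0.05, the 4 tags named passed with the same direction, 12 or 13 of the 13 tags of the longest rising run were called, except 10 under the filter of 10 CPM, which tests fewer tags, and 12 or 13 of the falling run were called. With the replicate block 2091 tags were called. No pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.035, -0.008 and -0.076, and none correlated best with its own number. These deviations are from means of 3 libraries, so the correlations constrain each other and cannot settle whether libraries were paired. Wild-type replicates 1, 2 and 3 correlated best with U1 replicates 3, 1 and 2, at 0.186, 0.123 and 0.168. A pairing, by these numbers or others, was therefore not excluded, and no fit took another numbering into account. Thinned to the smallest library, 2002 tags were called. At these library sizes 70.1% of simulated 1.5-fold changes were recovered; depth was not varied there. The list tests were not run, since the lists had no members.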

Other observations

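The tests in this part were chosen after the values had been seen, except for the other splits of the libraries.

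Some tags were read in neither strain. Of the 11488 tags, 678 had no read in any of the 6 libraries, and 260 of these stood in 26 stretches of 5 or more consecutive tags, the longest of 30. In 1000 shuffles of the tag order there was at most 1 such stretch and none longer than 5 tags (permutation p = 0.001, the smallest these shuffles can give). Fold changes over windows of 50 tested tags stayed within narrow bounds upward, with a highest window median of 0.16 on the log2 scale. The lowest window median was -0.44, below the -0.25 that 1000 shuffles reached, and that window held 22 falling and 3 rising tags.

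The run of 13 called tags that holds AKAW_06019 was read in U1 and almost unread in wild type. Reads of another strain or species in the U1 libraries remain open: 0 of the 7 tags unread in wild type and at 1 CPM or more in U1 lay outside the run, which leaves a strain that differs at this run alone possible. Whether the genes are missing from the wild-type genome or silent in it cannot be told apart, because 4 of the 13 tags had more than 3 wild-type reads and such reads could come from similar genes elsewhere. Switching on of a silent gene cluster in the mutant may be proposed as a biological hypothesis. DNA reads of both strains would show whether the genes are present in wild type, but not what switched them on. A difference in the stage of the cultures also stays open for this run and could not be tested.

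The run of 13 abundant tags that fell in U1 is a second pattern. Scaling set by a few abundant genes is argued against, since the median log2 fold change of the run nearest to 0 under any of the 5 other scalings was -1.88. Full loss of the genes from the U1 genome is argued against by the lowest count of any of these tags in any U1 library, 87. This holds only if such reads did not come from similar genes elsewhere, which was not tested. A difference in regulation between the strains and a difference in the stage of the cultures stay open and could not be tested, because the labels give no time points.

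Neighbouring tags tended to change together beyond these runs. Fold changes of adjacent tested tags correlated at r = 0.445 (Spearman's rho = 0.174) across tags, which are not independent replicates, and no shuffle of the tag order exceeded 0.058. The 2 longest runs alone did not account for it, since r was 0.227 (rho = 0.168) without them. Reads shared between overlapping neighbours are argued against as the whole cause, since without the runs r was still 0.082 at 2 tested tags apart, above the 0.036 of the shuffles, although it was -0.012 at 5 apart. Gain of a segment of 50 or more tested tags is argued against by the highest window median of 0.16, below the 0.58 of a 1.5-fold gain, while shorter segments were not examined and shared regulation of neighbours stays open, untested.

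Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, called 2153 tags, and the highest of the others called 0. With 10 splits the share cannot fall under 0.05. Each of the other splits put libraries of both strains in both groups. The strain difference then counted as spread within groups, so calls were unlikely and their absence does not measure chance calls.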
